A study of Mus musculus with 8 samples.

How the data were processed

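The 8 samples were from mice, 6 profiled with an antibody against Foxp3, the transcription factor that defines regulatory T (Treg) cells, and 2 with a non-specific IgG antibody. Per the labels, all cells were sorted from the thymus of C57BL/6 mice as CD45+CD4+CD8-CD25+ cells positive for a Foxp3-Thy1.1 reporter. One genotype carried wild-type Foxp3 (WT) and the other a mutant Foxp3 called DSM. The labels do not spell out DSM. Each genotype had 3 Foxp3 libraries and 1 IgG library, and groups and replicate numbers were taken from the sample titles. The labels name the assay Cut&Tag, whereas their protocol describes CUT&RUN, in which pA/G-MNase bound to the antibody cuts nearby DNA. The protocol used 500000 cells per biological replicate. It does not say whether the replicates came from separate mice, so p-values of comparisons between libraries measure the spread between these samples. The other p-values take genome positions, genes or regions as units and do not measure that spread.

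Per the submitters' processing notes, BWA, MACS2 and edgeR were used with mouse build mm9, with no versions given, and edgeR results were not analysed here. The deposited files were 8 peak lists in the 10-column MACS2 narrowPeak layout, called separately for each sample. Peaks were not pooled over replicates. The authors' deposited score per peak equalled 10 times the −log10 q value cut to a whole number in 100% of the peaks. The deposited fold enrichment per peak is a ratio of the summit pileup to the expected pileup. The deposited −log10 p and −log10 q values were used as given, and the lowest −log10 q was 1.301, which corresponds to a q of 0.05. Scores, folds and p-values belong to the authors' lists and were used to describe, rank or filter peaks within a list. The lists hold no read counts, so the depth of each library in reads is unknown.

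Relative depth was reconstructed from the MACS2 definitions of fold and p, which give the number of tags at each summit, the expected number and the factor that scaled the library to its control. All peaks of all lists were solved within a tolerance of 0.0005 on the −log10 p scale. The median over other scaling factors was 0%, leaving aside the fitted factor divided by whole numbers, which can fit too. The largest fitting factor was taken, so tag numbers rest on that choice. The background per base of each Foxp3 list was 0.991 to 1 times that of the IgG list of its own genotype, and tag numbers are given relative to the DSM IgG library. Where an enrichment is given for a region, it is the scaled number of tags at the highest summit divided by the library's genome-wide expected number, as mean ± SD over the libraries with a peak there. It was computed only where a peak was called, so it describes called peaks. Simulated lists with known scaling at 4 values gave back 100% of the summit tag numbers.

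Genome sequence and annotation were NCBIM37, the assembly behind mm9, with GENCODE M1 genes, and chromosome names and lengths matched the peak lists. Coordinates are 1-based mm9 positions. Peaks on chromosomes 1 to 19, X and Y were kept. Peaks of the 6 Foxp3 lists that overlapped by at least 1 bp were merged into regions. A region was called recurrent in a genotype when at least 2 of its 3 libraries had a peak there. Chance overlap was taken from 100 circular shifts of each list along the chromosomes, for which the smallest possible p is 0.0099. A promoter was the 1 kb on either side of a transcript start of a protein-coding gene. Regions outside promoters were assigned to coding exons, untranslated regions, introns or intergenic sequence, in that order.

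The 13 gene lists with 259 entries were fixed before the data were examined, and 252 entries matched a protein-coding gene directly and 5 through an older symbol. A gene counted when a recurrent region lay in its body or within 10 kb. Each list was compared with 10000 random lists matched on gene length in 10 bins (one-sided permutation test), and Benjamini-Hochberg adjustment was made over the 26 tests of 13 lists and 2 genotypes, with a threshold of 0.05. The IgG lists were tested the same way as a family of their own. The forkhead sequence TGTTTAC was counted on both strands in the 200 bp around region centres, against windows 2 kb to either side, with an exact permutation of the 3 windows within each region (two-sided). A further 7 sequences and the share of peak summits with each were compared between genotypes with the exact permutation test of 3 against 3 libraries. That test has 20 assignments and a smallest two-sided p of 0.1, so no comparison of library values could pass 0.05. Confidence intervals of shares are 95% Wilson intervals and cover counting error only.

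Named regions were the 10 highest by mean within-list score percentile among regions outside both IgG lists, for each of 3 classes: a peak in all 6 Foxp3 libraries, a peak in at least 2 WT and 0 DSM libraries, and the reverse. Per gene list, up to 8 members with a recurrent region were named by the number of libraries with a peak. Foxp3, Il2ra, Ctla4, Ikzf2, Tnfrsf18, Il2 and Ifng were always named. This rule was fixed before the data were examined.

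Each step was tested on simulated data. Of 200 regions planted per class in shifted lists, all were recovered for shared regions and for regions of either genotype alone, over 25522 regions. Unplanted regions called in the same simulation numbered 0 shared, 1 of WT alone and 20 of DSM alone. Gene lists with a region planted at 50% of the members were called in 100% of 20 rounds for each genotype over 22225 genes, and 1.92% (DSM) and 2.69% (WT) of unplanted lists had a raw p under 0.05. Those rates hold for regions shifted to random positions, not for real peaks, which gather near certain genes. Housekeeping genes passed the same permutation test in both IgG lists (adjusted p = 0.000433 for both), so the rates do not calibrate the calls on real peaks. A motif share of 6% against a background of 3% was detected in 92% of 200 simulations at the number of WT regions and in 100% at that of DSM, and an unraised share in 2.5% and 6%. Alternatives comprised a stricter threshold, lists cut to the 593 best peaks, another overlap, removal of IgG regions, recurrence in all 3 libraries, other gene windows, another motif, all sequences, and leaving out each library. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.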

Results

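Foxp3 occupancy was profiled in thymic CD4+CD25+ T cells that expressed either wild-type Foxp3 (WT) or the DSM mutant, to ask where each form of the protein was bound and whether the mutant occupied other sites. The 3 WT libraries held 3666, 750 and 593 peaks on the standard chromosomes, and the 3 DSM libraries held 12219, 1072 and 6663. The IgG libraries, 1 per genotype, held 8221 peaks in WT and 9839 in DSM. Foxp3 peaks had median widths of 156 to 191 bp. The 6 Foxp3 lists merged into 15200 regions, of which 848 were recurrent in WT and 5119 in DSM.

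Peaks of both genotypes fell at a shared set of regions. In total, 552 regions were recurrent in both genotypes, which was 65.1% of the WT recurrent regions and 10.8% of the DSM ones, against 0 in each of 100 circular shifts (permutation p = 0.0099, the smallest they can give). Overlap of DSM recurrent regions with DSM IgG peaks also exceeded such shifts (41.9% against 0.197%). The shifts therefore do not show that the sharing was particular to Foxp3. Of the shared regions, 251 lay outside both IgG lists. Of the 552, 81 had a peak in all 6 libraries and 45 of the 81 lay outside both IgG lists. The highest ranked lay 12.5 kb from the nearest transcript start, that of Cap1, an actin regulator (chromosome 4, 122575695 to 122575975, intergenic), with 48.6 ± 9.49 times the background in WT and 59.8 ± 8.22 in DSM (SD, n = 3 each). The next was the promoter of Dnajc12, a co-chaperone gene (chromosome 10, 62848939 to 62849423), at 67.5 ± 8.43 in WT and 66.1 ± 15.3 in DSM (SD, n = 3 each). An intronic region of the translation factor gene Eif4e3 (chromosome 6, 99472319 to 99473611), 143.8 kb from the nearest transcript start, stood at 78.8 ± 8.24 and 85.7 ± 5.69 (SD, n = 3 each). The promoter of Dennd4c (chromosome 4, 86393754 to 86394745) stood at 87.4 ± 2.83 and 74.6 ± 21.0 (SD, n = 3 each). The other 6 lay near Ern1, which encodes an endoplasmic reticulum stress sensor, in introns of the ATP-gated channel gene P2rx7 and of Ssbp2, at the promoter of the Mediator gene Med23, and near Gapt and the non-classical MHC gene H2-T23. Without WT replicate 1 or 2, or DSM replicate 1 or 3, the shared count fell to 195, 331, 192 and 202. It was 251 outside the IgG lists, 147 in the best-scoring 50% of each list and 52 in lists of equal length.

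Occupancy recurrent in WT without any DSM peak was found at 124 regions, 67 of them outside both IgG lists. The highest ranked of the 67 lay in an intron of Aim2, a cytosolic DNA sensor (chromosome 1, 175328748 to 175329171), at 71.3 ± 23.8 times the background in 3 WT libraries and with a TGTTTAC site. Next came an intergenic region 154.1 kb from the start of Tgfbr2, a TGF-beta receptor gene (chromosome 9, 116238338 to 116238549), at 43.0 ± 10.6 (SD, n = 3). A region nearest to the start of Ptpn22, which encodes a phosphatase that restrains T cell receptor signalling, was in an intron of Bcl2l15 (chromosome 3, 103654793 to 103654910) at 45.0 ± 1.46 (SD, n = 2). Ptpn22 was not a WT-only gene, since 4 WT and 5 DSM recurrent regions lay within 10 kb of it. The intergenic region whose nearest start was that of Nfkbiz, an NF-kappaB regulator, was 238.9 kb away (chromosome 16, 55583172 to 55583532), and the promoter of the interferon-induced gene Oasl2 (chromosome 5, 115347297 to 115347491) stood at 36.3 ± 3.66 (SD, n = 3), with a TGTTTAC site. Ninj2, Gm6189, Ms4a6b, 2310046O06Rik and Auh completed the 10. The 124 became 262 without DSM replicate 1, 29 without WT replicate 1 and 59 without WT replicate 2.

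DSM occupancy without any WT peak was recurrent at 3441 regions, 1780 of them outside both IgG lists. Promoters of Tmem106b (chromosome 6, 13019632 to 13019876), at 67.2 ± 4.83 times the background (SD, n = 2), and of Apool (chromosome X, 109424885 to 109425229), at 57.5 ± 11.3 (SD, n = 2), ranked highest. An intergenic region 10.8 kb from the start of Senp7, a SUMO protease gene (chromosome 16, 56064603 to 56064791), stood at 80.5 ± 18.3 (SD, n = 3), and the promoter of Spryd4 (chromosome 10, 127648779 to 127649157) at 58.4 ± 2.79 (SD, n = 3). An intron of Ifih1, an RNA sensor gene (chromosome 2, 62468591 to 62468844), stood at 52.8 ± 11.1 (SD, n = 3). Introns of BC046404 and Arpc2, the promoter of Atp5k and intergenic regions nearest to Tmem121 and Ptma made up the rest. The 3441 fell to 451 without DSM replicate 1 and to 534 without DSM replicate 3, and it was 1586 in the best-scoring 50% of each list.

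Other groupings of the libraries gave regions of 1 side alone as well, and among the 10 splits of the 6 libraries into 3 and 3, the 2 one-sided counts reached 130 for the smaller and 4428 for the larger in other splits. With each list cut to its 593 best peaks, 234 regions were recurrent in WT and absent from DSM and 226 the reverse. The total of 460 was the highest of the 10 splits, the next being 246, and 10 splits cannot give a share under 0.1. Of those 234 WT regions, 200 had a peak in a full DSM list, and 69 of the 226 DSM regions had one in a full WT list. Libraries of the same genotype shared on average 0.764 of the regions of the shorter list, against 0.537 for libraries of different genotypes, a difference of 0.227 (exact one-sided p = 0.1, the smallest possible with 10 splits). The difference was 0.0538 (exact p = 0.5) without DSM replicate 2, which shared 42.3%, 22.5% and 23.6% with the 3 WT libraries.

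**Figure D1:**
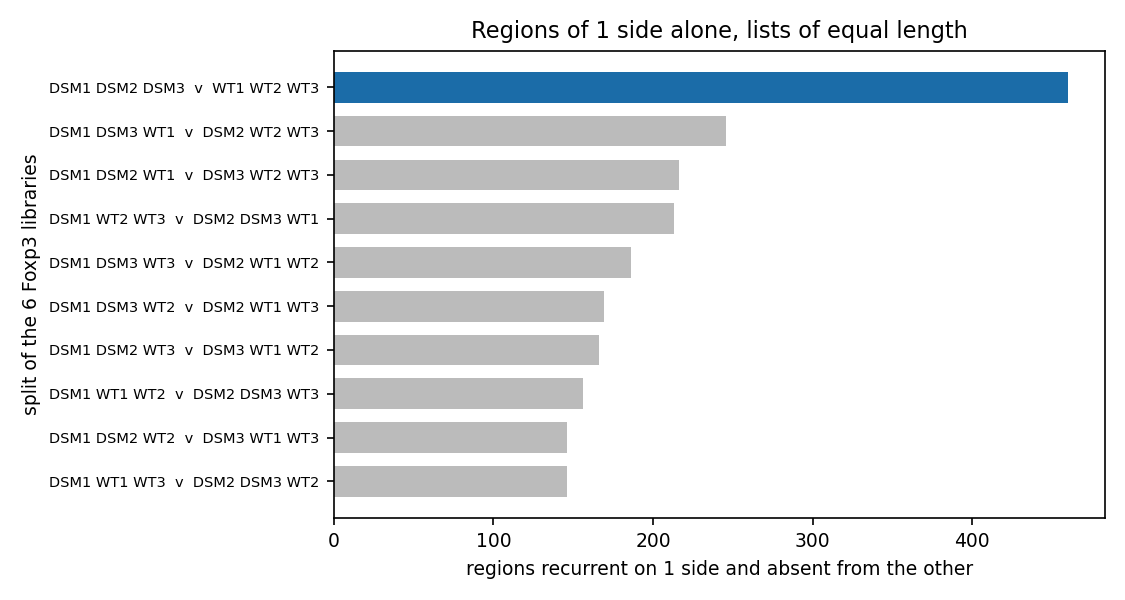
Regions recurrent on 1 side of a split and absent from the other (x axis, number of regions) for each of the 10 splits of the 6 Foxp3 libraries (y axis), with every list cut to its 593 best peaks. The split by genotype (blue) gave 460 regions and the other splits (grey) 146 to 246.

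Among 8 sequences counted under the peaks, 7 had every library of 1 genotype above every library of the other in the full lists, and none passed an adjusted p of 0.05. The forkhead sequence TGTTTAC, the class of site bound by Foxp3 and its relatives, lay within 100 bp of 8.66% ± 1.88 of WT summits and 5.39% ± 1.08 of DSM summits (SD, n = 3 each, exact p = 0.1, adjusted p = 0.114 over 8 sequences), against 2.68% and 2.53% in the DSM and WT IgG lists. With lists of equal length, a comparison chosen after the data were seen like the other subsets of summits, the shares were 9.61% ± 0.675 and 5.90% ± 0.169 (SD, n = 3 each, exact p = 0.1). Outside both IgG lists they overlapped, at 8.38% ± 2.08 and 5.98% ± 1.48 (SD, n = 3 each, exact p = 0.2). The wider forkhead sequence RYAAACA lay under 27.7% ± 4.13 of WT and 18.8% ± 2.05 of DSM summits, and outside both IgG lists under 27.5% ± 2.73 and 21.0% ± 2.10 (SD, n = 3 each, exact p = 0.1 for both). The RUNX sequence TGYGGT stood at 29.3% to 31.9% in the 3 WT libraries and 23.7% to 26.7% in the 3 DSM libraries (exact p = 0.1). The AP-1 sequence TGASTCA stood at 8.18% ± 0.296 in WT and 6.40% ± 0.721 in DSM (SD, n = 3 each, exact p = 0.1). A repeat of 4 TTTG units lay under 1.77% ± 0.591 of WT and 0.713% ± 0.0566 of DSM summits, and in 0.0852% and 0.0813% of the WT and DSM IgG summits (Foxp3 SD, n = 3 each, exact p = 0.1). Windows 2 kb away held the repeat in 0.696%, 0.533% and 0.506% for WT replicates 1 to 3. For DSM replicates 1 to 3 they held it in 0.704%, 0.373% and 0.638%, against 0.720%, 0.653% and 0.765% at summits. IgG summits lay below their own flanks (0.809% in WT and 0.727% in DSM), so they are a low baseline for this repeat.

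The core of the CTCF site, an architectural protein of chromatin, and the GC box went the other way. The CTCF core CCRCYAGRKGG lay under 6.33% ± 0.783 of DSM and 4.69% ± 0.318 of WT summits (SD, n = 3 each, exact p = 0.1), against 0.925% and 0.973% in the DSM and WT IgG lists. The GC box GGGCGG, frequent in promoters, stood at 25.7% ± 0.602 in DSM and 18.4% ± 3.19 in WT (SD, n = 3 each, exact p = 0.1), below the 43.8% and 45.9% of the IgG lists. Away from promoters the GC box shares overlapped, at 9.11% ± 0.931 in DSM and 7.93% ± 1.31 in WT (SD, n = 3 each, exact p = 0.3), and the WT minus DSM difference, -7.29 percentage points in the full lists, was -3.93 in lists of equal length, -2.88 outside both IgG lists and -4.85 in the best-scoring 50% of each list. The ETS sequence MGGAAG overlapped between the genotypes in the full lists, with 39.5% ± 0.904 in DSM and 40.4% ± 1.55 in WT (SD, n = 3 each, exact p = 0.5), but not in lists of equal length, with 32.5% to 36.9% in the 3 DSM libraries and 38.6% to 41.1% in the 3 WT libraries (exact p = 0.1). In lists of equal length the CTCF core (8.94% ± 1.32 in DSM and 5.90% ± 2.07 in WT, exact p = 0.2) and AP-1 (6.86% ± 0.832 and 7.64% ± 0.682, exact p = 0.6) overlapped between genotypes (SD, n = 3 each).

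**Figure D2:**
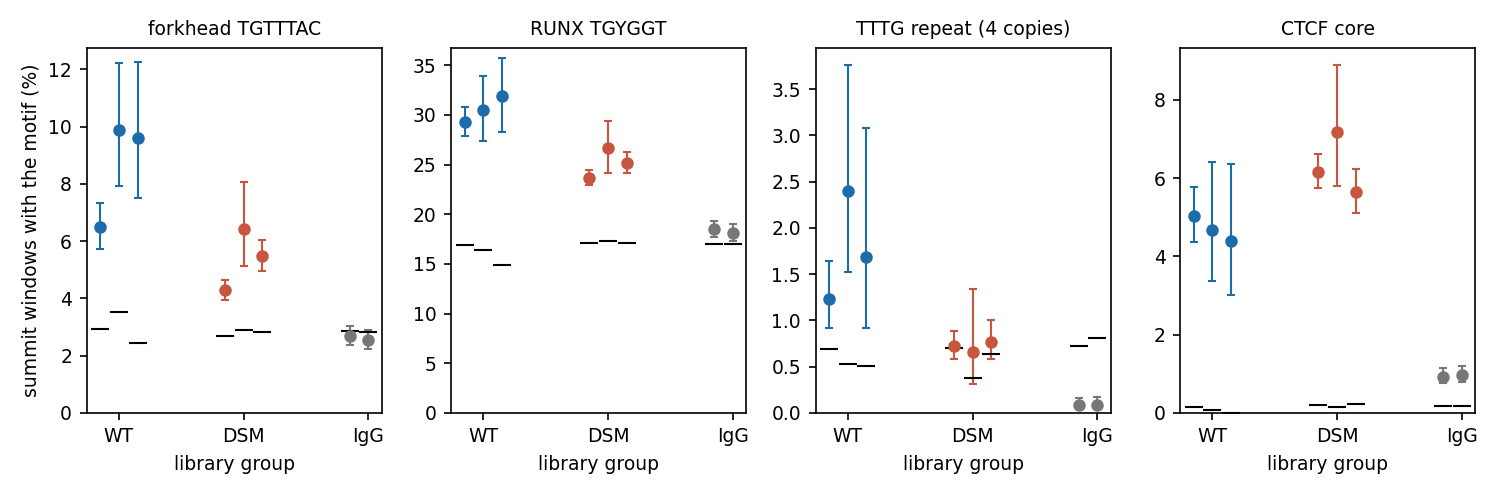
Share of peak summits with each sequence in the surrounding 200 bp (y axis, %) per library, for Foxp3 in WT, Foxp3 in DSM and IgG, with 95% Wilson intervals as bars and the share in windows 2 kb away as black dashes. Forkhead shares were 6.49% to 9.87% in WT and 4.28% to 6.44% in DSM, and CTCF core shares 4.38% to 5.02% in WT and 5.64% to 7.18% in DSM.

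Over merged regions, TGTTTAC was more frequent at the centre of recurrent regions than at their flanks in both genotypes. The share was 8.25% of 848 WT regions against 3.13% at the flanks (exact permutation p = 3.49e-08) and 5.04% of 5118 DSM regions with flanks on the chromosome against 2.73% (exact permutation p = 6.11e-13). The DSM excess of 2.32 percentage points was 4.26 without DSM replicate 1 and 4.41 without DSM replicate 3, and the WT excess of 5.13 was 7.72 without WT replicate 1. In lists of equal length the excess was 4.92 in DSM and 7.58 in WT, and the difference in excess between the genotypes was not tested. Of the regions of 1 genotype alone there, 23 of 234 in WT and 11 of 226 in DSM held TGTTTAC (Fisher's exact p = 0.0498, adjusted p = 0.199 over 8 sequences). RYAAACA lay in 75 and 44 of them (Fisher's exact p = 0.00278, adjusted p = 0.0222). That test takes regions as units and covers no spread between libraries. Among the 81 regions with a peak in all 6 libraries, the share with TGTTTAC was 16.0% at the centre against 3.09% at the flanks (exact permutation p = 0.000567). With the wider forkhead sequence RYAAACA, the WT excess over the flanks was 12.6 percentage points and the DSM difference was -0.00977.

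Recurrent Foxp3 regions lay close to genes of T cell identity. Of 36 Treg signature genes, 9 had a recurrent WT region within 10 kb, 6.91 times as many as in random lists (adjusted p = 0.0013), among them Cd83, Ctla4, Entpd1, Ikzf2, Ikzf4, Nt5e, Rgs1 and Tnfrsf1b. In DSM 19 of the 36 had one, against 8.51 in random lists (adjusted p = 0.00186). The region in an intron of Ikzf2, which encodes Helios (chromosome 1, 69590817 to 69591200), had a peak in 2 WT and 3 DSM libraries. An intronic region of Ctla4, an inhibitory receptor gene (chromosome 1, 60970200 to 60970535), had one in 1 WT and 2 DSM libraries, and the region of Ikzf2 lay in both IgG lists and that of Ctla4 in the DSM one. Il2ra, the CD25 gene, had a DSM-only region in an intron (chromosome 2, 11575062 to 11575284, 2 DSM libraries) that lay in both IgG lists. Within 10 kb of Foxp3 itself, the most recurrent region was in an intron of the neighbour Ppp1r3f (chromosome X, 7148060 to 7148196), with a peak in 2 DSM and 0 WT libraries. Tnfrsf18 (GITR) had no recurrent region, with 2 regions of 1 DSM library each, and the cytokine genes Il2 and Ifng had none. The IgG lists covered 28 (DSM) and 27 (WT) of the 36 Treg genes, against 15.9 and 14.4 in random lists (adjusted p = 0.000433 for both). Outside both IgG lists, 13 of 36 remained in DSM (adjusted p = 0.0026) and 3 of 36 in WT, 4.64 times as many as in random lists (adjusted p = 0.0768).

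Genes of T cell receptor signalling and costimulation were the list with the lowest adjusted p in DSM. Regions lay near 7 of 29 members in WT, 5.38 times as many as in random lists (adjusted p = 0.00173), and near 22 of 29 in DSM, against 7.17 (adjusted p = 0.0013). The intronic region of Itk, a kinase downstream of the receptor (chromosome 11, 46157282 to 46157956), had a peak in all 6 libraries but also in both IgG lists. Regions of Cblb, a ubiquitin ligase gene (chromosome 16, 52129586 to 52130000), and Lck (chromosome 4, 129247347 to 129247569) had peaks in 3 WT libraries and in 2 and 1 DSM libraries, and both lay in the DSM IgG list. A region over a coding exon of Cd3d (chromosome 9, 44794343 to 44794869) counted for Cd3d and Cd3g and lay in both IgG lists. Cd2, Prkcq and Ubash3a had regions in 3 DSM libraries, of which that of Cd2 lay in both IgG lists, that of Prkcq in the DSM one and that of Ubash3a in neither. The IgG lists covered 21 of 29 each (adjusted p = 0.00988 in DSM and 0.00404 in WT). The counts outside both IgG lists were 5 of 29 in WT and 18 of 29 in DSM (adjusted p = 0.000867 for both). The DSM count was 7 of 29 without DSM replicate 1 or without DSM replicate 3 (adjusted p = 0.00433 and 0.0156), and the WT count 3 without WT replicate 1 and 4 without WT replicate 2 (adjusted p = 0.0342 and 0.0193).

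T cell transcription factor genes numbered 6 of 28 in WT (adjusted p = 0.0166) and 16 of 28 in DSM (adjusted p = 0.00186). The 6 were Bach2, Foxo1, Foxp1, Lef1, Tcf7 and Tox. An intronic region of Foxp1, a forkhead relative of Foxp3 (chromosome 6, 99007085 to 99007508), had a peak in all 6 libraries and in both IgG lists. Intronic regions of Lef1 (chromosome 3, 130860274 to 130860612) and Tcf7 (chromosome 11, 52079189 to 52079443), related effectors of Wnt signalling, had peaks in 3 WT and 2 DSM libraries, and that of Lef1 lay outside both IgG lists and that of Tcf7 in the DSM one. Tox had a region in 2 WT and 3 DSM libraries, also outside IgG. Elf1 and Ikzf1 had recurrent regions in DSM. IL-2 and STAT5 targets numbered 3 of 18 in WT (Bcl2, Ccnd3 and Osm, adjusted p = 0.0442) and 11 of 18 in DSM (adjusted p = 0.00186), with Ccnd2 and Nfil3 occupied in 3 DSM libraries and no WT library at their most recurrent region, and Bcl2l1, Gadd45b and Socs3 among the DSM members. The DSM and WT IgG lists covered 23 and 24 of the 28 transcription factor genes (adjusted p = 0.00065 and 0.000433) and 16 and 15 of the 18 IL-2 and STAT5 targets (adjusted p = 0.000433 and 0.00065). Outside both IgG lists, transcription factor genes numbered 4 of 28 in WT (adjusted p = 0.0364) and 15 of 28 in DSM (adjusted p = 0.000867), and IL-2 and STAT5 targets 3 of 18 in WT (adjusted p = 0.0108) and 7 of 18 in DSM (adjusted p = 0.0078). The WT call for IL-2 and STAT5 targets was lost without WT replicate 1 or 2 (1 of 18 in both, adjusted p = 0.343 and 0.575), without DSM replicate 1 or 3 (adjusted p = 0.0659 and 0.078), in lists of equal length (2 of 18, 8.52 times random lists against 5.30 in the full lists, adjusted p = 0.142) and within 50 kb (4 of 18, adjusted p = 0.0804).

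**Figure D3:**
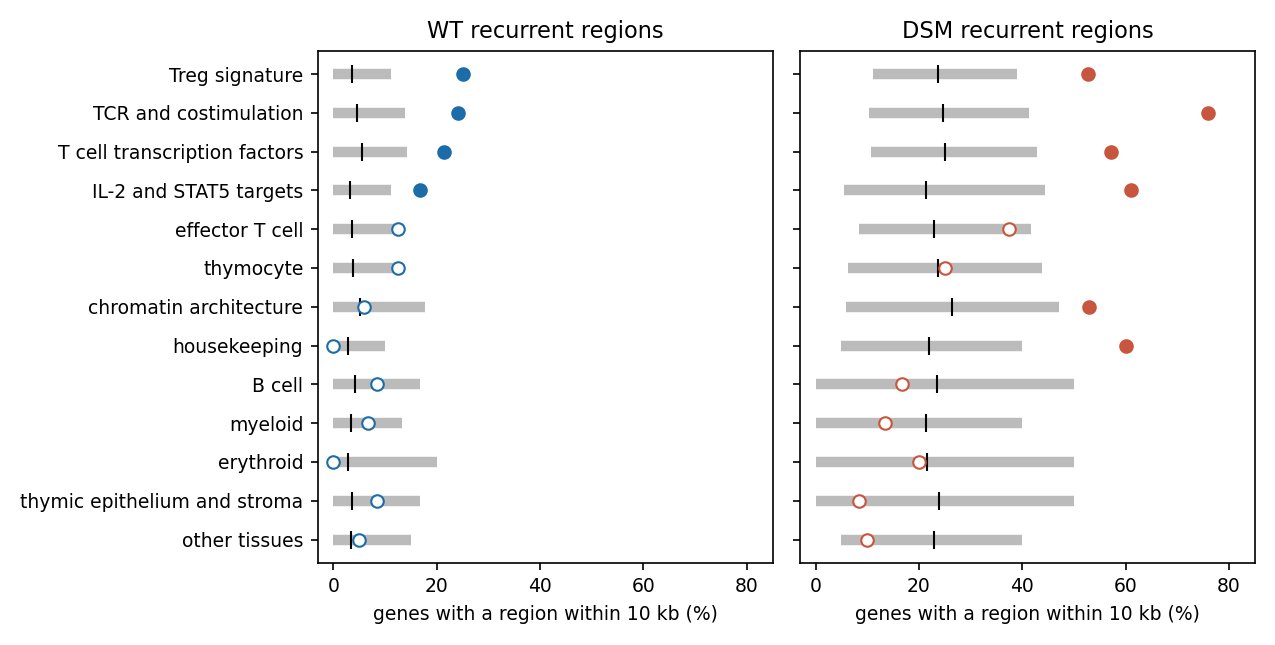
Share of each gene list with a recurrent region in the gene body or within 10 kb (x axis, %) for WT and DSM, with lists on the y axis. Filled points passed an adjusted p of 0.05, open points did not, and the grey bar and black tick give the 95% range and mean of 10000 random lists of the same size and gene lengths. Treg signature genes stood at 9 of 36 in WT and 19 of 36 in DSM.

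Housekeeping and chromatin architecture genes passed the test in DSM and not in WT. Random lists gave means of only 0.582 and 0.868 genes with a WT region for these lists. Failing in WT therefore does not show a difference between the genotypes. Housekeeping genes had a DSM region for 12 of 20 members (adjusted p = 0.00186) and a WT region for 0 of 20, with a peak at the Actb and Ppia promoters in 3 DSM libraries, and near Eef2, Rplp0, B2m, Pgk1, Hnrnpa2b1 and Hsp90ab1 in 2. Of these named regions, that of Hsp90ab1 lay outside both IgG lists and all others lay in both. The IgG lists covered 19 (DSM) and 18 (WT) of the 20 housekeeping genes, and outside both IgG lists 5 of 20 remained in DSM, 2.61 times as many as in random lists against 2.73 times before (adjusted p = 0.0886). Chromatin architecture genes had a DSM region for 9 of 17 (adjusted p = 0.0486) and a WT region for 1, with a peak near Nipbl, the cohesin loader gene, Hdac7, Med1 and Smarca4 in 3 DSM libraries, and near Rad21, Smc3, Satb1 and Arid1a in 2. The regions of Hdac7, Med1, Smarca4, Rad21 and Smc3 lay in both IgG lists and that of Arid1a in the WT one. Those of Nipbl and Satb1 lay in neither. The IgG lists covered 14 (DSM) and 13 (WT) of the 17 (adjusted p = 0.0106 and 0.0147). Outside both IgG lists 3 of 17 remained, 1.22 times as many as in random lists against 2.01 times before (adjusted p = 0.623), and the call for chromatin architecture genes was also lost without WT replicate 1 or 2 (adjusted p = 0.0608 and 0.054). Effector T cell genes did not pass, with 3 of 24 in WT (Gata3, Pde3b and Ptpn22, adjusted p = 0.128) and 9 of 24 in DSM (adjusted p = 0.16), among them Fasl, Stat4, Zap70 and a single intergenic region counted for Il4 and Il13. Pde3b, a phosphodiesterase gene, had an intronic region in all 6 libraries (chromosome 7, 121623314 to 121624026) that lay in both IgG lists. Outside both IgG lists, effector genes numbered 7 of 24 in DSM (adjusted p = 0.0409).

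Neither the thymocyte list nor any list of markers of other cell types passed the test. Thymocyte genes numbered 2 of 16 in WT (Cd1d1 and Cpa3) and 4 of 16 in DSM (Cd1d1, Dtx1, Il7r and Lyl1), with adjusted p = 0.24 and 0.787. Outside both IgG lists the counts were still 2 of 16 and 4 of 16. These were 7.23 times random lists in WT against 3.29 before (adjusted p = 0.0796), and 2.24 times in DSM against 1.05 (adjusted p = 0.202). B cell markers numbered 1 of 12 and 2 of 12, myeloid markers 1 of 15 and 2 of 15, erythroid markers 0 of 10 and 2 of 10, thymic epithelium and stroma genes 1 of 12 in each genotype, and genes of other tissues 1 of 20 and 2 of 20 in WT and DSM (lowest adjusted p = 0.656). Several of these regions belonged to neighbours, as the region counted for Cr2 was at the promoter of Cr1l, that for Klf1 at Dnase2a, that for Cd14 at Tmco6 and that for Fcer2a at Trappc5. Pecam1 had its highest ranked region in 2 WT libraries and Mbp an intronic region in 2 libraries of each genotype, while Epor, Fcgr1 and Ckm had regions in 2 DSM libraries.

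The list results changed when single libraries were left out. Only the receptor signalling list passed in DSM without DSM replicate 1 or without DSM replicate 3, and in WT without WT replicate 1. In lists of equal length, 5 of 29 receptor signalling genes and 5 of 28 transcription factor genes passed in WT (adjusted p = 0.0078 for both) and no list passed in DSM. Treg signature genes numbered 2 of 36 in WT there, against a mean of 0.534 in random lists (adjusted p = 0.369). That was 3.74 times random lists, against 6.91 in the full lists. With few genes left, the DSM counts were 3 of 28 for transcription factors (5.07 times random lists, against 2.27 in the full lists), 2 of 29 for receptor signalling (3.34 against 3.07) and 1 of 18 for IL-2 and STAT5 targets (3.59 against 2.85). Chromatin architecture genes numbered 1 of 17 (2.54 against 2.01). For these lists the lost calls do not show a lower enrichment. Treg signature and housekeeping genes numbered 0 of 36 and 0 of 20 in DSM. Random lists gave means of only 0.639 and 0.298 there, so a lower enrichment could not be told from too few regions. The difference between the genotypes in a list was not tested.

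Foxp3 peaks lay at promoters less often than IgG peaks in both genotypes, and DSM libraries had the higher promoter share. Promoters held 40.3% ± 1.65 of DSM peaks and 30.1% ± 3.24 of WT peaks (SD, n = 3 each, exact p = 0.1, the smallest possible), against 59.0% and 61.5% of DSM and WT IgG peaks. The Foxp3 lists appeared to be called against the IgG library of their own genotype, which takes sites of high IgG signal out of them. A promoter share below that of IgG peaks therefore does not show where Foxp3 was bound. Introns held 26.6% ± 0.511 in DSM and 33.3% ± 2.43 in WT, and intergenic sequence 30.8% ± 1.84 and 34.5% ± 0.998 (SD, n = 3 each, exact p = 0.1 for both). With lists of equal length the promoter difference was 6.69 percentage points (exact p = 0.2), against 10.2 in the full lists.

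Many Foxp3 regions coincided with IgG peaks. Of the DSM recurrent regions, 41.9% lay in a peak of the DSM IgG list and 43.1% in one of the WT IgG list. Of the WT recurrent regions, 26.2% lay in the WT IgG list and 49.2% in the DSM IgG list. Shifted positions gave 0.197% (DSM) and 0.193% (WT) for the own list (permutation p = 0.0099 for both, the smallest possible). Among the 124 regions of WT alone, 46 lay only in the DSM IgG list and 3 only in the WT IgG list. Among the 3441 regions of DSM alone, 140 lay only in the DSM IgG list and 350 only in the WT one. Exact binomial tests of these counts against an even split gave p = 6.98e-11 for WT alone and 8.52e-22 for DSM alone, which cover counting error over regions only. The split was not even over all 15200 regions, of which 1162 lay only in the DSM IgG list and 798 only in the WT one. With 1 IgG library per genotype, the differences could not be tested against the spread between IgG libraries. In the best-scoring 50% of all lists the own-IgG shares were 14.2% in DSM and 4.14% in WT. With the Foxp3 lists cut to 593 peaks and the IgG lists left whole, 52.6% of the 234 regions of WT alone lay in the DSM IgG list and 19.2% in the WT one, against 28.3% and 40.3% of the 226 regions of DSM alone.

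The number of peaks varied widely within each genotype. The geometric mean was 4436 in DSM and 1177 in WT, a ratio of 3.77 (exact p = 0.2, n = 3 each). The ratio was 2.27 without DSM replicate 1, 7.67 without DSM replicate 2 and 6.65 without WT replicate 1, and it was 5.61 at a q of 1e-05 or below, a threshold chosen after the data were seen. The reconstructed tag numbers were 1.19, 1.39 and 1.00 for WT replicates 1 to 3 and 0.991, 1.04 and 1.02 for DSM replicates 1 to 3, relative to the DSM IgG library, and the WT IgG library stood at 0.819.

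**Figure D4:**
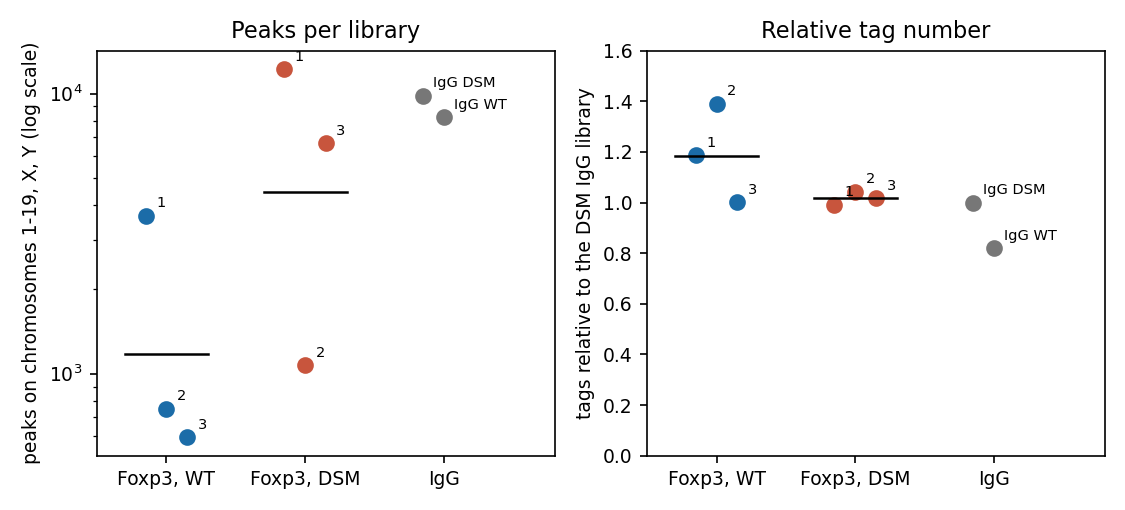
Peaks per library on chromosomes 1 to 19, X and Y (left, log scale) and reconstructed tag number relative to the DSM IgG library (right), for Foxp3 in WT, Foxp3 in DSM and IgG, with replicate numbers beside the points and black lines at the geometric means of 3 libraries. DSM replicates 1 and 3 had 12219 and 6663 peaks at 0.991 and 1.02 relative tags, and WT replicate 2 had 750 peaks at 1.39.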

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

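The alternatives were fixed before the data were examined, except the q of 1e-05, the flanks 10 kb away and the motif shares at summits by subset and without each library. Direction and side of the threshold were kept for list length, replicate similarity, promoter share and the WT forkhead excess in every setting run, with ranges over left-out libraries of 2.27 to 7.67, 0.0538 to 0.297, 8.28 to 11.1 and 5.13 to 7.72, and of 2.30 to 4.41 for the DSM forkhead excess. The first 3 cannot pass 0.05 in this design. Most counts of recurrent regions moved with list length. In lists of equal length, WT alone gave 234, DSM alone 226 and shared 52. With recurrence in all 3 libraries they were 23, 434 and 81, with IgG regions removed 67, 1780 and 251, and at a q of 1e-05 or below 49, 1188 and 53. In the top 50% of each list by score, DSM alone gave 1586, shared 147 and WT alone 116. Left-out libraries gave 29 to 262 for WT alone, 451 to 4498 for DSM alone and 192 to 536 for shared. Fewer peaks enter these counts by construction.

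Gene lists that passed numbered 0 in DSM and 2 in WT at equal list length, 1 and 0 with recurrence in all 3 libraries, 2 in WT in the top 50% and 1 in WT within 5 kb of a transcript start. Left-out libraries gave 1 to 6 in DSM and 1 to 4 in WT. Of the 26 list tests, the call was lost in 9 with recurrence in all 3 libraries, in 6 without DSM replicate 1 or without DSM replicate 3, in 4 without WT replicate 1 and in 2 without WT replicate 2 or within 50 kb. Housekeeping and Treg signature genes fell to 0 near DSM regions at equal list length, and IL-2 and STAT5 targets to 0 near WT regions within 5 kb of a transcript start. The share of recurrent regions in the own IgG list was 0 for both genotypes at equal list length, where the IgG lists were shortened too. The DSM forkhead difference was -0.00977 percentage points with motif RYAAACA, and the cause was not tested. All 8 motif differences at summits kept their sign in 4 subsets and without each library, but not their size. Away from promoters the WT minus DSM difference of the GC box was -1.17 percentage points against -7.29 (exact p = 0.3) and RUNX shares overlapped between genotypes (exact p = 0.2), as did AP-1 shares there and in the top 50% (exact p = 0.2 for both). At equal list length the ETS difference was 4.67 percentage points against 0.883 (exact p = 0.1). Of the 30 named regions, 26 at equal list length and 30 in the top 50% kept their number of libraries with a peak. List length cannot be compared in lists of equal length.

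With the replicate number as a block, the peak ratio stayed 3.77 and the promoter difference 10.2 percentage points (exact sign-flip p = 0.25 for both, the smallest possible), and replicate similarity was 0.207. Same-numbered libraries shared 49.5% of the shorter list and others 55.7%, and the deviations in peak presence of same-numbered pairs correlated at -0.227, -0.137 and -0.0829. List-length deviations from the genotype mean (log10) were 0.440 in DSM and 0.493 in WT for replicate 1, and -0.617 and -0.196 for replicate 2. For replicate 3 they were 0.177 and -0.298, of opposite sign. With 3 pairs, these values cannot tell whether same-numbered samples were processed together. The lists hold no read counts, and differences at single sites were not tested.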

Other observations

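Thymocyte genes held a peak in different numbers in the 2 IgG libraries. Of 16 such genes, 6 had a peak in the DSM IgG list and 1 in the WT IgG list, while Treg signature genes (28 and 27 of 36) and T cell transcription factor genes (23 and 24 of 28) were covered alike. There was 1 IgG library per genotype, so this difference was not tested.

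Of the tests below, those of masking by the DSM control, of tag number and of the forkhead share in subsets of summits were chosen only after the result was seen. Regions recurrent in WT without a DSM peak lay in the DSM IgG list more often than in the WT one, and the expected tag number at Foxp3 summits followed the IgG pileup of the own genotype more closely than the other (mean difference of Spearman's rho 0.124, above 0 in 6 of 6 lists), as calls against the own IgG library would give. Masking by the DSM control may account for part of the 124 regions, but 54.0% of them lay outside both IgG lists, against 51.7% of the 3441 regions of DSM alone. This argues against masking by overlapping IgG peaks as the whole cause. It cannot exclude masking by IgG signal below the peak threshold, which needs no called IgG peak. At equal list length the split by genotype gave 1.93 times as many regions of 1 side alone as the highest other split outside both IgG lists (236 against 122), which argues against a difference only where IgG peaks lie. In the full lists, 3 of the 10 splits gave a smaller one-sided count as large as 124 (highest other 130) and 2 gave a larger one as large as 3441 (highest other 4428), and 10 splits are too few for a share under 0.05. IgG signal below the peak threshold stays open, as does a difference between wild-type and mutant Foxp3, which the design names.

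DSM lists were longer than WT lists, by 3.77 times in geometric mean. More tags in the DSM libraries would not account for this, since DSM had 0.860 times the tags of WT. The WT control was shallower, at 0.819 of the DSM one, and with DSM pileups scaled down to that depth the ratio was still 3.08. That is a simulated bound, so the depth of the control cannot be told apart from an effect of genotype, and the ratio did not pass the exact test.

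The forkhead sequence was more frequent at WT than at DSM summits, by 3.26 percentage points. At equal list length the difference was 3.71 points and away from promoters 3.29 points, with every WT library above every DSM library in both, which argues against longer lists and promoter peaks as the cause. Outside both IgG lists it was 2.40 points and the genotypes overlapped, so dilution by IgG-like peaks may contribute and could not be excluded, although for the wider forkhead sequence RYAAACA the difference there was 6.51 points with every WT library above every DSM library. A difference between wild-type and mutant Foxp3 in how often it was bound at forkhead sites, which the design names, also stays open and was not tested apart from these.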
